A study of Mus musculus with 3 samples.

How the data were processed

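Spleen T cells of mice were profiled by droplet single-cell sequencing. Per the labels, cells were enriched with a magnetic T cell kit, each of the 10 samples was stained with its own barcoded antibody (a hashtag) and with barcoded antibodies against 7 surface proteins, and live CD11b-negative, MHC class II-negative, CD90.2-positive, CD6-positive, CD5-positive cells were sorted. Sorting took 3 days at 2 to 4 samples per day, cells of 2 time points were pooled, and each pool was loaded into 2 wells of 12000 cells with 5000 to 6000 expected back. The labels list 3 libraries made from the pooled cells, an mRNA library, a hashtag library and a surface protein library, each with 1 entry. The library type given for the hashtag and surface protein entries is the reverse of their titles. The surface protein library was not analysed here.

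The authors deposited whole-number UMI counts per gene and cell barcode. Per the submitters' processing notes, reads were aligned and counted with Cell Ranger 2.1.1 on mm10 and handled with Seurat 3, while the software named in the deposited gene matrix header is 3.0.1, so the version is open. The deposited hashtag counts are whole numbers per tag and barcode, with an additional line for counts not matched to a tag, and the tool that made them is not given in the sources used here. Whether reads or UMIs of the tags were counted is not stated, so no interval is given for tag counts. The other deposited values are gene symbols, hashtag names and barcodes. The gene matrix held 64586 barcodes with 1 shared suffix, which therefore did not tell wells apart, and 31054 features, of which 1 was an added LAT-IRES-eGFP sequence and 8633 had no UMI. Of the hashtag library counts, 14.6% were not matched to a tag and were left out.

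Everything below was computed from those counts with Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, leidenalg 0.10.2 and R 4.3.3. Barcodes were joined between the matrices and assigned to hashtags with HTODemux of Seurat 5.3.0 (quantile 0.99). Cells with 1 hashtag, at least 200 genes and at most 10% mitochondrial UMIs were kept. HTODemux accepts a tag from a few counts upwards, and barcodes called with more than 1 hashtag were treated as doublets. Scrublet, run through Scanpy 1.11.5, marked 5 of the 42954 kept cells, which for this number of cells means that the caller had not worked, so doublets of 2 cells with the same hashtag remain. Counts were scaled to 10000 per cell and log-transformed, the 2000 most variable genes seen in at least 10 cells were taken to 30 principal components, and cells were clustered on 15 nearest neighbours with the Leiden method at resolution 1.0. Genes of the 10 fixed gene lists, receptor variable segments, immunoglobulin, mitochondrial, ribosomal protein, Xist and Y-linked genes were left out of the clustering genes.

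The design was fixed before the data were examined. This covers the 17 marker sets for naming clusters, the 10 gene lists with 156 genes, the comparisons, the filters, the alternatives and the rule for naming genes. The naming procedure that applied the marker sets was written afterwards. Special T classes (regulatory, follicular helper, gamma-delta, innate-like, interferon-response, cycling) needed 2 own markers among the 10 leading genes and 3 markers at a fold of 2, and cells other than T cells needed 3 own markers among them. Naive and effector names needed a Cd4 to Cd8 ratio of 3 either way and 3 markers at a fold of 1.5, but did not need an own marker among the leading genes. Of the CD4 effector-like clusters 1, 4, 6 and 8 the leading genes hold 0, 1, 1 and 0 own markers, and clusters 6 and 8 each hold 1 regulatory T marker. The own marker of cluster 6 is Cd4, which also stands in the naive CD4 set. A cluster was given a non-T name only where its CD3 transcripts were under 0.8 times those of the median cluster. Clusters that met no rule were left unnamed. Of the listed genes 154 matched a symbol in the files. Cd244a and Ly108 did not. The checkpoint list shares 5 genes with the surface protein list, the receptor list shares 2 with the type 2 list and 1 with the B-cell help list, and Gzma, Il7r and Il2ra also stand in a marker set (NK cells, naive CD4 cells, regulatory T cells).

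No label or file says which hashtag carried which genotype. The planned tests between genotypes were therefore not run, hashtags are treated as samples in no group, and no hashtag was given a genotype from its values. Each class comparison sets summed UMIs of 1 class against those of another as CPM (UMIs of a gene relative to the sum of all UMIs of the class, on the usual CPM scale) and their ratio. Ratios carry exact 95% conditional intervals, levels exact Poisson intervals and shares exact binomial (Clopper-Pearson) intervals. All intervals cover counting error only, and none holds the spread between mice. No p-value is given, since none is made from cells and hashtags in no group are not used as replicates. A gene counted as higher or lower where its ratio was at least 1.5 either way, its interval left out 1, it had at least 100 UMIs in 1 of the classes, and the direction was the same in every hashtag with at least 50 cells of both classes. Genes under 100 UMIs in both classes were not measurable. Genes to be named were, in each list, the 4 measurable members with the largest ratio each way whose interval left out 1. Called genes outside this rule are named in some places and were chosen after their values were seen. These are Il4, Maf, Gata3, Izumo1r and Ubash3b for CD4 effector-like, Socs1 and Themis for regulatory T-like, Prkcq for CD8 effector/memory-like, Il13 for follicular helper T-like, Il7r, Stat3 and Crtam for gamma-delta T-like, and Il4ra, Stat6 and Jun for cycling-like cells. Some called genes stay in the counts and are not reported here by name. A ratio against 0 UMIs was taken against a floor of 3 counts over the class.

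On simulated counts with 200 genes changed 2-fold, the calls for CD4 effector-like against naive-like cells recovered 100 of 100 raised and 99 of 100 lowered genes among 10037, called 29 of 9837 unchanged genes, and 95.4% of intervals held the true ratio. For regulatory T-like against naive-like cells, 100 and 97 of 100 were recovered among 5430 genes, with 5 of 5230 unchanged genes called and 95.7% of intervals holding the true ratio. For CD8 effector/memory-like against naive-like cells, 99 and 99 of 100 were recovered among 8771 genes. Of 8571 unchanged genes 10 were called, and 95.0% of intervals held the true ratio. The simulated counts held counting error only, without spread between hashtags, and the rule on direction in hashtags was not run on them. Coverage near the set level follows from that. These rates therefore do not tell how many of the reported calls, which join different hashtags, are wrong.

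Alternatives covered other hashtag rules, cell filters, clustering settings and scalings, cells thinned to 2000 UMIs, the median over hashtags, and leaving out each hashtag in turn. A ratio within the hashtag that held both classes was added for the comparisons of effector with naive cells. Gene positions come from the GENCODE vM21 annotation of GRCm38, the assembly that mm10 names.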

Results

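The data describe T cells sorted from mouse spleen. Per the labels, the mice carried a mutated form of Lat (LatY136F), alone or together with a knockout of Stat6 or of Grap2. The protocol also names wild-type mice and the design text does not, so whether a hashtag is wild type is open. Lat encodes the membrane adaptor on which the T cell receptor assembles its signalling complex, Grap2 an adaptor that links this complex to SLP-76, and Stat6 the transcription factor that acts downstream of the interleukin-4 receptor. The series title names the lymphoproliferative disorders that follow a defective LAT signalling complex and asks how loss of Stat6 or Grap2 modulates them. The 10 samples were told apart by hashtags 1 to 10, and since neither the labels nor the files used here tie a hashtag to a genotype, values are given for each hashtag and no genotypes are compared.

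The gene matrix held 513282823 UMIs, with up to 112008 UMIs per barcode and a median of 6491 UMIs and 2207 genes. HTODemux called 50912 barcodes (78.8%, 95% interval 78.5 to 79.1) with 1 hashtag, 12288 with more than 1 and 1386 (2.15%) with none. The numbers depend on the method. A simpler rule, in which the leading hashtag has at least 10 counts and 4 times those of the next, called 3277 (5.07%) with more than 1 and 4390 (6.80%) with none, and a rule of 3 counts and 2 times called 2093 (3.24%) with more than 1. Hashtag 6 alone was called for 3910 barcodes by HTODemux and for 6324 by the first of these rules, which left 3836 and 6197 kept cells. Hashtag 3 went the other way, with 4792 and 3540 barcodes and 3975 and 2949 kept cells. Its tags were the weakest, with a median of 14 tag counts per kept cell, against 45 to 139 in the other hashtags. Among all barcodes 10536 (16.3%) were over the mitochondrial limit and 45 were under the gene minimum. The 42954 kept cells had a median of 7041 UMIs and 2319 genes. They numbered 2890, 3205, 3975, 5837, 5361, 3836, 5247, 6045, 3062 and 3496 for hashtags 1 to 10, with 20073069 (hashtag 9) to 63807110 UMIs (hashtag 5) in total and a median of 5874.5 (hashtag 10) to 9693 UMIs (hashtag 5) per cell. The share of barcodes over the mitochondrial limit ran from 1.89% in hashtag 6 to 27.0% in hashtag 1.

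Effector, cycling and gamma-delta T cells made up most of the pool, and CD4 naive T cells came almost entirely from 1 hashtag. Clustering gave 26 clusters, of which 21 met the naming rules, and these formed 12 classes. CD4 effector-like cells were 31.3% of all kept cells (13448 cells, 30.9 to 31.7), CD8 effector/memory-like cells 14.1% (6062 cells, 13.8 to 14.4), cycling-like cells 10.7% (4612 cells) and gamma-delta T-like cells 9.67% (4154 cells, 9.39 to 9.95). Interferon-response T-like cells were 7.53% (3236 cells), follicular helper T-like cells 2.13% (915 cells) and regulatory T-like cells 0.803% (345 cells, 0.721 to 0.892). CD4 naive-like cells were 3.93% (1689 cells, 3.75 to 4.12) and CD8 naive-like cells 2.99% (1285 cells, 2.83 to 3.16). These shares depend on the settings. At resolution 0.5 and with at most 5% mitochondrial UMIs no CD4 naive-like cluster was named and CD8 naive-like cells were 6.54 and 7.10%, the latter with CD8 effector/memory-like cells at 8.18%. Without hashtags 1 to 5 the shares were 7.68% (CD4 naive-like), 5.70% (CD8 naive-like), 1.23% (regulatory T-like), 5.24% (CD8 effector/memory-like) and 15.4% (gamma-delta T-like), and without hashtags 1, 2 and 4 CD8 effector/memory-like cells were 5.72%.

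The classes were spread very unevenly over the hashtags. CD4 naive-like cells were 54.4% of hashtag 9, which held 1665 of the 1689, and at most 0.252% of any other hashtag. CD8 naive-like cells were 32.8% of hashtag 9 and 3.805% of hashtag 8. CD4 effector-like cells ran from 0.934% of hashtag 1 to 95.7% of hashtag 7, with a median of 11.7%. CD8 effector/memory-like cells ran from 0.0572% of hashtag 10 to 61.6% of hashtag 1 (median 6.62%), and gamma-delta T-like cells from 0.156% of hashtag 6 to 91.2% of hashtag 10 (median 2.02%). Cycling-like cells ran from 0.359% of hashtag 9 to 28.2% of hashtag 4 (median 5.44%) and interferon-response T-like cells from 0.143% of hashtag 10 to 20.8% of hashtag 4 (median 5.46%). Follicular helper T-like cells ran from 0.173% of hashtag 1 to 5.67% of hashtag 5. Without hashtag 9 the pooled share of CD4 naive-like cells was 0.0602%, that of CD8 naive-like cells 0.702% and that of regulatory T-like cells 0.444%, and without hashtag 10 the share of gamma-delta T-like cells was 2.44%. Of the 26 clusters, 12 drew over 50% and 6 over 90% of their cells from 1 hashtag, so a class and a hashtag are often nearly the same set of cells.

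Some clusters were named for cells other than T cells, although the sort removed CD11b-positive and MHC class II-positive cells. They were 637 myeloid-like cells (1.48%, up to 5.40% of hashtag 2), 370 erythroid-like cells (0.861%, up to 4.40% of hashtag 4) and 64 B-like cells (0.149%), nearly all under hashtags 1 to 5. The name erythroid-like rests on a few of its cells, since Hbb-bs was seen in 11.4% of them and Ccl5 in 61.6%, at a median of 1248.5 UMIs, so the 370 cannot be counted as erythroid cells. Another 6137 cells (14.3%), among them 49.2% of hashtag 8, lay in 5 unnamed clusters. The largest of these, cluster 5 with 3169 cells, 93.6% of them from hashtag 8, was led by Ccl5, Gzmk, Klrb1f, Itga4 and Eomes, and 34.0% of its cells had Cd4 and no Cd8 transcripts while 34.6% had Cd8 and no Cd4 transcripts. Cluster 10, with 1931 cells, 90.6% of them with Cd8 and no Cd4 transcripts, was led by the cytotoxic and NK-receptor genes Gzma, Klra8, Gzmm and Klre1. Cluster 19, with 885 cells, was led by the haemoglobin gene Hbb-bs and the macrophage genes C1qa, C1qb, C1qc and Hmox1, cluster 24, with 132 cells, by the basophil proteases Mcpt8 and Prss34, and cluster 26, with 20 cells, by Vcam1, Slc40a1, Hmox1, C1qc and C1qa.

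**Figure D1:**
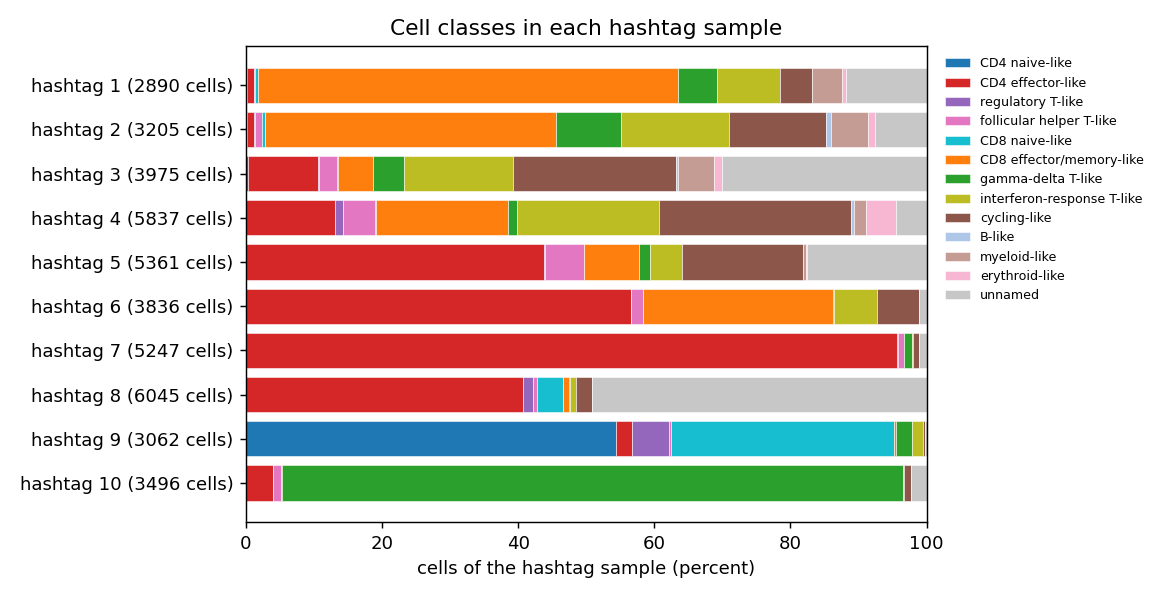
Stacked horizontal bars give the share of each cell class among the kept cells of each hashtag sample, in percent, with the number of cells beside each hashtag. Hashtag 7 holds 95.7% CD4 effector-like cells, hashtag 10 holds 91.2% gamma-delta T-like cells, and hashtag 9 holds 1665 of 1689 CD4 naive-like cells.

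The genes targeted in the study differed in level between hashtags, and all were detected in every hashtag. Over the T cell clusters Lat ran from 238 CPM (232.7 to 242.4) in hashtag 3 to 512 CPM (504 to 521) in hashtag 6, with a median over hashtags of 329. Stat6 ran from 24.1 CPM (22.9 to 25.4) in hashtag 5 to 75.0 CPM (72.4 to 77.6) in hashtag 8, with a median of 45.8. Grap2 ran from 68.7 CPM (66.6 to 70.7) in hashtag 5 to 310.2 CPM (303 to 318) in hashtag 9, with a median of 97.4. Hashtag 9 is also the one with 54.4% CD4 naive-like cells, which had Grap2 at 305 CPM against 89.9 in CD4 effector-like cells. Among CD4 T-like cells alone Lat ran from 280.5 (hashtag 9) to 608 CPM (hashtag 5), Stat6 from 28.7 (12.4 to 56.6, 38 cells of hashtag 1) to 104 CPM (hashtag 8) and Grap2 from 59.3 (hashtag 5) to 296 CPM (hashtag 9). Lat (ENSMUSG00000030742) lies on chromosome 7 from 126363824 to 126369570 on the minus strand of GRCm38, Stat6 (ENSMUSG00000002147) on chromosome 10 from 127642986 to 127660957 and Grap2 (ENSMUSG00000042351) on chromosome 15 from 80572594 to 80652854, both on the plus strand. All of them are protein-coding. The libraries count 3′ tags, which do not read a point mutation upstream and may stay after part of a gene is deleted, so these levels do not check the genotypes, and no hashtag was assigned one from them.

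**Figure D2:**
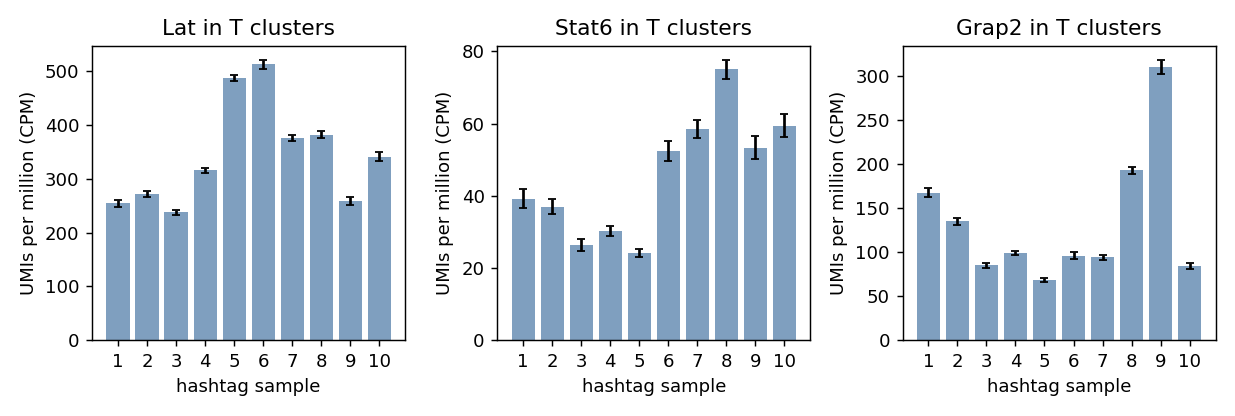
Bars give the CPM of Lat, Stat6 and Grap2 in the T cell clusters of each hashtag sample, with exact Poisson 95% intervals as error bars. Lat is highest in hashtag 6 (512 CPM), Stat6 in hashtag 8 (75.0 CPM) and Grap2 in hashtag 9 (310.2 CPM).

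CD4 effector-like cells were compared with CD4 naive-like cells (13448 against 1689 cells). Of 16 measurable type 2 genes 7 were higher, beside 53 of 137 over all lists, and no enrichment was tested. Il1rl1, which encodes the interleukin-33 receptor chain ST2, stood at 155 against 1.30 CPM, a ratio of 119 (69.5 to 223), and the chemokine receptor Ccr4 had a ratio of 77.5 (26.5 to 376). The cytokine Il4, at 31.0 (18.8 to 55.4), and the transcription factors Maf, at 44.5 (38.2 to 52.1), and Gata3, at 11.5 (10.6 to 12.5), were also higher and are named after their values were seen. Lower in the effector-like cells were Cd27, a costimulatory receptor, at 0.194 (0.185 to 0.203), Cd247, the zeta chain of the receptor complex, at 0.240 (0.228 to 0.253), and Grap2, at 0.295 (0.283 to 0.307). Per the labels, some mice carried a knockout of Grap2 or Stat6, and their hashtags are not known. Ratios of Grap2 and Stat6, here and in the comparisons below, can therefore mix knockout with other cells and cannot be read as traits of a class. Leaving out hashtag 7 moved Il1rl1 to 29.3, and leaving out hashtag 9 moved Cd27 to 0.310, Cd247 to 0.436 and Grap2 to 0.614. Values without hashtag 9 rest on 6, 6, 10 and 2 CD4 naive-like cells of hashtags 1, 2, 3 and 5. No hashtag is then left to check directions. Il4 was at 8.33 without hashtag 9, and Maf and Gata3 at 23.8 and 7.26 without hashtag 7.

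These ratios set the cells of many hashtags against naive-like cells of 1 hashtag, since hashtag 9 held 1665 of the naive-like but 71 of the effector-like cells. Within hashtag 9 alone Maf was at 22.3 (17.7 to 28.1), Ccr4 at 50.8 (10.9 to 314), Il4 at 7.26 (1.74 to 23.1) and Gata3 at 2.34 (1.71 to 3.13), while Il1rl1 was at 1.95 (0.0460 to 13.0), an interval that includes 1. Cd27, at 0.941 (0.763 to 1.15), and Cd247, at 0.994 (0.785 to 1.24), did not differ there beyond counting error, and Grap2 was at 0.689 (0.546 to 0.858). Of the 154 genes, 53 were higher, 14 lower and 137 measurable in the pooled comparison. The lower genes numbered 9 without hashtag 9, 9 when cells were thinned to equal UMIs and 24 with the median over hashtags. Here that median is the ratio of hashtag 9 alone, called without asking that the interval leave out 1. Within hashtag 9 the counts were 21 higher and 7 lower of 80 measurable, and 11 of the higher and 4 of the lower genes were called in both.

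By list, no type 2 gene was lower. In the LAT and proximal receptor signalling list 7 of 28 were higher, among them the inhibitory receptors Cd6, at 2.63 (2.47 to 2.80), and Cd5, at 2.54 (2.43 to 2.66), and 4 were lower, with Cd247, Grap2 and Cblb among them. In the list of receptor-induced and anergy genes 5 of 18 were higher and 2 lower. They include the transcription factor Irf4, at 14.9 (9.72 to 24.1), and the ubiquitin ligase Rnf128, at 11.5 (5.23 to 31.3), on the higher side and Nr4a1, at 0.479 (0.404 to 0.571), on the lower. Of the checkpoint and ectoenzyme genes 10 of 16 were higher, with Bhlhe40 at 86.6 (42.0 to 215), the ectoenzyme Entpd1 (CD39) at 69.2 (42.6 to 121) and Tigit at least 26.5-fold higher against a floor of 3 counts, and Cd27 was the 1 lower. Of the type 1 and cytotoxic genes 8 of 18 were higher, with Tbx21 at 70.2 (19.4 to 580) and Il18rap at 35.7 (20.9 to 67.2), and 3 were lower, with the perforin gene Prf1 at 0.159 (0.132 to 0.193). Rora, at 11.6 (9.21 to 14.9), was the 1 higher of 3 type 17 genes, and 4 of 7 B-cell help genes were higher, with Tnfsf11 at 10.2 (7.61 to 14.1) and Tnfsf8 at 2.97 (2.71 to 3.26). Of the cytokine receptor and STAT genes 5 of 20 were higher, with Socs2 at 54.5 (25.0 to 149), and 3 were lower, with Il6st at 0.0282 (0.0249 to 0.0320) and Il6ra at 0.176 (0.166 to 0.186). Of the dissociation stress genes 5 of 11 were higher and 1, Jun at 0.226 (0.208 to 0.245), lower. Of the genes of stained surface proteins 5 of 8 were higher and 1 lower, and 5 of these 6 also stand in the checkpoint list. Leaving out hashtag 9 moved Cd6 to 6.82, Cd5 to 5.12, Entpd1 to 19.9, Il18rap to 8.31, Rora to 4.96, Tnfsf11 to 4.01, Tnfsf8 to 1.90, Il6st to 0.0814 and Il6ra to 0.398, and it ended the calls of Cblb (0.847), Nr4a1 (0.712) and Prf1 (0.543). As given above, these values rest on very few naive-like cells. Leaving out hashtag 7 moved Irf4 to 8.91 and Tbx21 to 106. Within hashtag 9 Bhlhe40 was at 10.9 (1.82 to 47.7), Entpd1 at 8.47 (2.41 to 24.5), Il18rap at 19.1, Irf4 at 7.26, Socs2 at 25.4, Tbx21 at 140, Rora at 20.2, Il6st at 0.465, Il6ra at 0.821 (0.627 to 1.06) and Jun at 0.479, and all but Il6st, Il6ra and Jun were under 100 UMIs there. Scaled to UMIs without ribosomal protein and mitochondrial genes, which took 30.5% of UMIs in the effector-like and 41.5% in the naive-like cells, every ratio fell by 0.25 on the log2 scale.

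Regulatory T-like cells were compared with CD4 naive-like cells (345 against 1689 cells). The cytotoxic protease gene Gzmb stood at 1041 against 3.10 CPM, a ratio of 336 (236 to 495), and Klrg1, a receptor of differentiated effector cells, had a ratio of 116 (69.7 to 209). Il1rl1 at 75.0 (43.1 to 143), Maf at 29.2 (24.8 to 34.6), Icos, a costimulatory receptor, at 12.6 (11.2 to 14.3) and Izumo1r, the folate receptor 4 gene of regulatory and anergic cells, at 5.15 (4.71 to 5.64) were higher too. Without hashtag 4 the Gzmb ratio was 123. Within hashtag 9, which held 168 of the regulatory T-like and 1665 of the naive-like cells, Gzmb was at 2.42 (0.898 to 5.63), Klrg1 at 22.1 (11.6 to 44.0), Il1rl1 at 22.4 (11.2 to 47.0), Maf at 16.4 (13.5 to 20.1), Icos at 4.37 (3.56 to 5.35) and Izumo1r at 5.90 (5.25 to 6.62). Without hashtag 9 Izumo1r was at 2.47. Here too, values without hashtag 9 rest on the very few naive-like cells given above, with no hashtag left to check directions.

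Of the 154 genes 31 were higher and 11 lower of 91 measurable, and within hashtag 9 alone 19 were higher and 5 lower of 81, with 15 and 4 called in both. Without hashtag 9 the lower genes numbered 3, and thinned to equal UMIs 19 were higher and 7 lower. With the median over hashtags, here hashtag 9 alone and without the interval rule, 5 were lower. Scaled to UMIs without ribosomal protein and mitochondrial genes, which took 29.2% and 41.5% of UMIs, every ratio fell by 0.28 on the log2 scale and the counts were 25 higher and 19 lower. By list, 4 of 6 type 2 genes were higher, namely Ccr4, Il1rl1, Maf and Gata3, with Ccr4 at 192 (64.5 to 941) and at 127 without hashtag 8, where its call ended. Of the receptor signalling genes 5 of 28 were higher, with Cd6 at 2.97 and Cd5 at 2.69 (10.3 and 6.78 without hashtag 9), though within hashtag 9 they were at 1.17 (0.956 to 1.42) and 1.44 (1.27 to 1.64) and not called, and 5 were lower, with Grap2 at 0.566 and Sos1 at 0.652, whose directions turned without hashtag 9 (1.02 and 1.30). Of the receptor-induced and anergy genes 3 of 12 were higher (Izumo1r, Tnfaip3 and Cd69), and of the checkpoint genes 3 of 6 (Itgae, Icos and Nt5e), of which Nt5e, at 3.57, was at 1.53 and not called without hashtag 9, as was Tnfaip3, at 2.65. The call of Cd69, at 1.65, ended without hashtag 6 or hashtag 9. Of the type 1 genes 3 of 6 were higher (Gzmb, Klrg1 and Il18r1) and Prf1 was lower, at 0.178 and without a call when hashtag 9 was left out (0.626). Il18r1, at 3.83, was at 25.8 without hashtag 9 and 2.34 without hashtag 8. Rora, at 21.4, was higher as the 1 measurable type 17 gene and was at 12.3 without hashtag 9. Of 5 B-cell help genes P2rx7 was higher, at 6.52, and Cd40lg, the CD40 ligand gene, lower, at 0.4995, and neither call held without hashtag 9 (1.74 and 0.835). Of the cytokine receptor and STAT genes 8 of 20 were higher, with Socs2 at 208 (94.4 to 570), Cish at 10.5 and Ifngr1 at 3.65 (3.28 to 4.07), and 3 lower. Socs2 was at 132 without hashtag 8. Of 7 dissociation stress genes Junb, at 2.45, and Jund, at 1.73, were higher and Jun, at 0.527, was lower, a call that ended without hashtag 9 (0.281) and within it (0.955). Among 6 genes of stained proteins 3 were higher, and 1 of these, Il2ra, is itself a marker used to name the class.

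CD8 effector/memory-like cells were compared with CD8 naive-like cells (6062 against 1285 cells). The granzyme genes Gzma, at 895 against 7.39 CPM with a ratio of 121 (98.0 to 152), and Gzmk, at 59.7 (42.7 to 86.3), were higher, Gzmk with 466 CPM in cluster 7 but 1.46 in cluster 2, which holds 3443 of these cells, as were the chemokine gene Ccl3, at 36.6 (15.6 to 113), and the gene of interferon-gamma, Ifng, at 29.9 (17.1 to 58.0). The receptor genes Il6st, at 0.147 (0.134 to 0.162), and Il6ra, at 0.391 (0.365 to 0.420), were lower. The class comparison joins different hashtags, since 1005 of the naive-like cells came from hashtag 9 and 230 from hashtag 8, most of these in cluster 23, which is rich in Ccl5 and had a median of 14231 UMIs. Leaving out hashtag 9 gave 56.8 for Gzma, 21.0 for Gzmk, 20.2 for Ccl3, 11.9 for Ifng and 0.393 for Il6st. Leaving out hashtag 8 gave 285 for Gzmk, 64.8 for Ccl3 and 63.3 for Ifng, and leaving out hashtag 1 gave 187 for Gzma. Within hashtag 8, with 53 against 230 cells, Gzma was at 135 (73.6 to 276), Gzmk at 25.3 (16.4 to 40.1), Ifng at 8.74 (2.86 to 26.7), Il6st at 0.2001 (0.0407 to 0.598) and Il6ra at 0.144 (0.0524 to 0.316). Since 223 of those 230 cells lie in cluster 23, which had Ccl5 at 7279 CPM against 341 in the other naive-like cluster, this check is not one against typical naive cells. Without cluster 23, a setting chosen after seeing the data with no hashtag left to check directions, Gzmk was at 1412 (against 0.125 CPM in the naive-like cells), Ifng at 125, Ccl3 at 63.7 and Rora at 6.04, and the calls of Ptpn6 (1.38), Izumo1r (1.34) and Ndrg1 (1.24) ended.

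Of the 154 genes 36 were higher and 15 lower of 120 measurable, and within hashtag 8 alone 19 were higher and 15 lower of 70, with 6 and 7 called in both. The lower genes numbered 27 with the median over hashtags, here hashtag 8 alone and without the interval rule. They numbered 29 at resolution 0.5 and 24 without hashtags 1 to 5. By list, 13 of 19 type 1 and cytotoxic genes were higher and none was lower. Of 7 type 2 genes 4 were higher, with Maf at 5.09 and Ccr4 at 9.51, which was at 4.72 without hashtag 9 and not called without hashtag 5. Of 28 receptor signalling genes 1, Ptpn6 at 1.53, was higher, a call that ended without hashtag 1, 2 or 8 (1.37 without hashtag 8), and 4 were lower (Sos1 at 0.556, Cblb and Cbl at 0.599, Prkcq at 0.621, not called without hashtag 9). Of 14 receptor-induced and anergy genes 2 were higher and 3 lower, and most of these calls rested on 1 hashtag. Izumo1r, at 1.75, was at 0.748 without hashtag 5 and 3.71 without hashtag 9, Ndrg1, at 1.74, was at 10.3 without hashtag 9 and not called without hashtag 1 or 8, and Egr3, at 0.337, and Egr1, at 0.496, were at 1.93 and 1.12 without hashtag 9. The call of Dgka, at 0.575, ended without hashtag 9 (0.769). Of 16 checkpoint genes 7 were higher, with Pdcd1 (PD-1) at 12.1 (6.73 to 24.5), or 7.68 without hashtag 5, and Itgae lower at 0.379, which turned to 3.23 without hashtag 9. Of 2 type 17 genes Rora was higher, at 3.69 (2.09 without hashtag 9), and of 4 B-cell help genes P2rx7 was higher, at 3.11 but not without hashtag 5 (1.49), and Tnfsf8 lower, at 0.576. Of 20 cytokine receptor and STAT genes 3 were higher, with Cish at 4.26, and 5 lower. Of 10 dissociation stress genes Fosb, at 2.80, and Hspa8, at 1.58 but not called without hashtag 9 (1.31), were higher and Jun, at 0.487, lower. Of 8 genes of stained proteins 4 were higher and 1 lower, with Entpd1 at 7.49 and the receptor constant gene Trbc2 at 1.68 on the higher side.

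**Figure D3:**
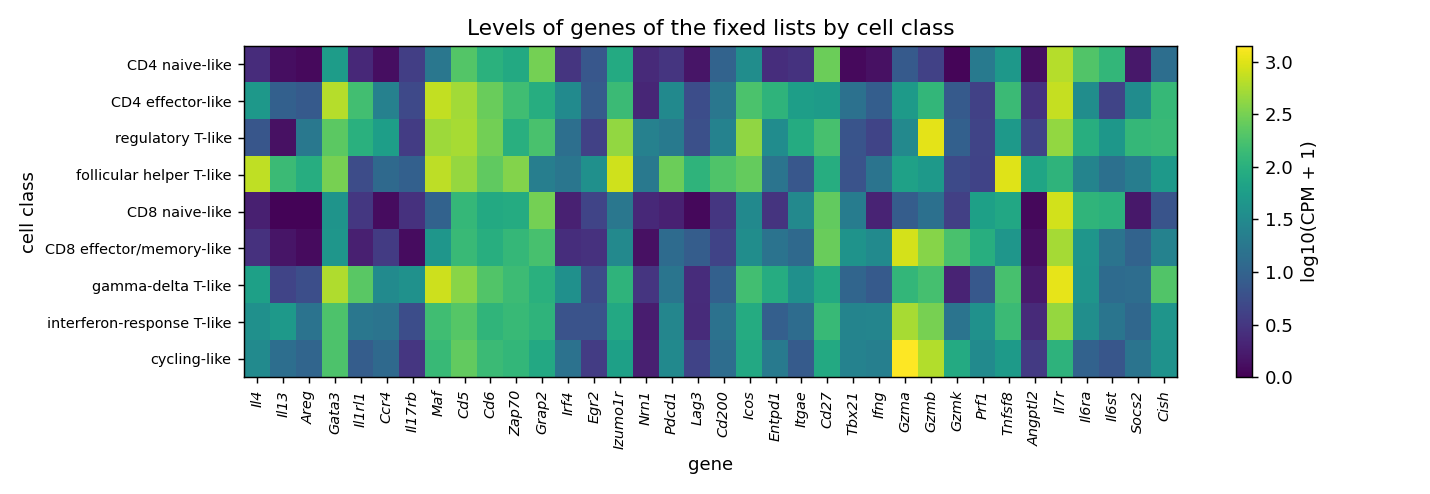
The heat map gives log10 of CPM plus 1 for 36 genes of the fixed lists (horizontal axis) in 9 T cell classes (vertical axis), from summed UMIs. Il4 and Tnfsf8 are brightest in follicular helper T-like cells, at 711 and 995 CPM, and Gzmb in regulatory T-like cells, at 1041 CPM. This Gzmb level is pooled over hashtags. Its ratio to CD4 naive-like cells was 336 pooled and 2.42 within hashtag 9.

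Follicular helper T-like cells were compared with all other T clusters (915 against 40816 cells) in levels of the listed genes. The own markers among the 10 leading genes of this cluster were Sostdc1 and Tbc1d4. Ccl1 led, at a fold of 38.4, and the markers Cxcr5, Bcl6 and Il21 were not among the leading genes, so the name is tentative. Il4 stood at 711 against 28.1 CPM, a ratio of 25.3 (24.5 to 26.1), and the epidermal growth factor family gene Areg and Il13 were at 15.3 (14.2 to 16.6) and 14.2 (13.3 to 15.1). The inhibitory receptor Lag3 was at 29.9 (27.6 to 32.5), Pdcd1 at 12.4 (11.8 to 12.9), Izumo1r at 10.3 (10.1 to 10.6) and the immediate-early factor Egr2 at 9.08 (8.07 to 10.2). Tnfsf8, the CD30 ligand gene, stood at 995 CPM with a ratio of 11.4 (11.1 to 11.6). Lower were Il1rl1, at 0.0703 (0.0506 to 0.0950) and at 0.149 without hashtag 7, and Grap2, at 0.171 (0.149 to 0.197). The limit given above for Grap2, which was knocked out in some mice, holds here too. Hashtags 3 to 6 had at least 50 cells of both sides, and the median ratio over them was 14.7 for Il4 and 11.6 for Areg. Il4, Tnfsf8 and Izumo1r were among the 10 leading genes of this cluster although they were kept out of the clustering genes.

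Of the 154 genes 49 were higher and 27 lower of 144 measurable. The B-cell help genes were the most one-sided list, with 6 of 8 higher and none lower, and Ascl2 at 69.8 (50.7 to 97.1) and Angptl2 at 48.8 (43.4 to 54.9). The call of Ascl2 ended without hashtag 4 or 5, with its ratio kept within 1.5 times. Of the checkpoint genes 11 of 16 were higher, with Cd200 at 18.5 and Tox2 at 9.39, and 2 lower, Itgae at 0.260 (0.146 without hashtag 5) and Entpd1 at 0.325 (0.527 without hashtag 7). Of the receptor-induced and anergy genes 10 of 19 were higher, with Nrn1 at 15.6 (10.3 without hashtag 1) and Nr4a3 at 9.11, and Ndrg1 was lower at 0.325. Of the receptor signalling genes 7 of 28 were higher, with the kinase Zap70 at 2.79 (2.70 to 2.89), Lcp2 (SLP-76) at 2.17 and Cd3g at 2.04, and 3 were lower, with Prkcq at 0.526 and Cbl at 0.626, not called without hashtag 8. Of the type 2 genes 6 of 18 were higher and 2 lower. The type 1 and cytotoxic list went the other way, with 13 of 19 lower and 1, Tnf at 4.23, higher. Gzmk was at 0.0587, Prf1 at 0.0840 and Gzma at 0.0792, or 0.0367 and 0.143 without hashtags 4 and 5. The other side includes clusters 5, 7 and 14, with Gzmk at 399, 466 and 315 CPM. Follicular helper T-like cells had Gzmk at 4.16 CPM, against 1.89, 14.4, 12.0 and 2.92 in CD4 effector-like clusters 1, 4, 6 and 8. A comparison with CD4 cells alone was not run. Il1r1 was the 1 higher of 5 type 17 genes, at 7.12. Of 20 cytokine receptor and STAT genes 5 were lower, with Ifngr1 at 0.138 and Il7r at 0.203, and Stat5a was higher at 2.26. Of 11 dissociation stress genes 3 were higher, with Jund at 2.12, and 2 lower, and of 8 genes of stained proteins 5 were higher, with Nt5e (CD73) at 2.92 and Il2ra at 2.67, and 2 lower.

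Few listed genes were called for gamma-delta T-like cells against the other T clusters (4154 against 37577 cells). A call needed the same direction in all 8 hashtags tested. Il17rb, the interleukin-25 receptor chain, was higher at 14.5 (13.3 to 15.9), or 9.06 without hashtag 10, as were Il7r at 2.17 (2.15 to 2.20) and Stat3 at 1.72 (1.66 to 1.78), whose calls ended without hashtag 10 (1.41 and 0.976), the feedback regulator Socs1 at 2.35 (2.27 to 2.42), or 1.5 without hashtag 10, and P2rx7 at 2.19 (2.07 to 2.32). Lower were Gzmk at 0.0144 (0.00965 to 0.0207), Ccl3 at 0.0356, Gzmm at 0.0472, Crtam at 0.132, Havcr2 at 0.286 and Areg at 0.560. Without hashtag 10, which held 3190 of these cells in cluster 3, the values were 0.0364 for Gzmk, 0.121 for Ccl3 (0.0232 without hashtag 3), 0.0833 for Gzmm, 0.439 for Crtam, 0.0336 for Havcr2 and 0.0523 for Areg, and without hashtag 4 Havcr2 was at 0.542 and Areg was no longer called. The Gzmk ratio also depends on the other side, which includes clusters 5, 7 and 14 with 399, 466 and 315 CPM. The class name rests on less in hashtags 7 and 9, where 12.1% of 58 and 19.7% of 71 gamma-delta T-like cells had Trdc, against 99.7% in hashtag 10. In hashtag 10, however, 84.1% of them also had Trac, against 40.1 to 70.7% in hashtags 1 to 5. Altogether 5 genes were higher and 6 lower of 143 measurable, and the higher genes numbered 9 without hashtag 9 and 9 without hashtags 1 to 5. The higher genes were 3 of 20 in the cytokine receptor list, 1 of 18 type 2 genes and 1 of 8 B-cell help genes. The lower ones were 4 of 19 type 1 genes, 1 of 16 checkpoint genes and 1 type 2 gene. None of the 28 receptor signalling, 19 receptor-induced, 4 type 17, 11 dissociation stress and 8 stained-protein genes was called. The rule also asked for agreement in hashtags 7 and 9, where few cells of the class had Trdc. In the effector against naive comparisons it asked for agreement in 1 hashtag, so the counts cannot be set side by side.

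Interferon-response T-like cells were compared with the other T clusters (3236 against 38495 cells, 8 hashtags tested). The class joins cluster 11, with 1718 cells, and cluster 13, with 1518 cells, which were CD4 and CD8 by the summed Cd4 to Cd8 ratio of the cluster. In cluster 11 49.8% of cells had Cd4 and no Cd8 transcripts and 26.3% had neither, and in cluster 13 89.6% had Cd8 and no Cd4 transcripts. Cluster 11 was led by the type 2 gene Il13, at a fold of 4.6, ahead of Ifit1 and Isg15 at 2.6. Il4 stood at 79.9 CPM in cluster 11 and 7.33 in cluster 13. Entpd1 was lower at 0.161 (0.141 to 0.184), with 0.283 without hashtag 7 and 0.106 without hashtag 5. Havcr2, at 0.201 (0.130 to 0.298), and Lag3, at 0.211 (0.152 to 0.286), which encode inhibitory receptors, were lower and stood at 0.0689 and 0.116 without hashtag 4. Prdm1, the Blimp-1 gene, at 0.284 (0.233 to 0.344), and Nrn1, at 0.470 (0.292 to 0.718), were lower as well. Of 144 measurable genes 1 was higher and 5 were lower, counts that depend on the settings. The lower genes numbered 26 without hashtags 1 to 5, 8 without hashtags 1, 2 and 4, 12 at resolution 2.0 and 2 when thinned, and the higher ones 2 or 3 under the median, thinning, resolution 2.0 or without hashtags 1 to 5. The higher gene was 1 of the 20 cytokine receptor and STAT genes. The lower genes were 4 of 16 checkpoint genes and 1 of 19 receptor-induced genes, and Entpd1 is also the 1 called among the 8 genes of stained proteins. In the joined class none of the 18 type 2, 28 receptor signalling, 19 type 1, 5 type 17, 8 B-cell help or 11 dissociation stress genes was called. The 2 clusters were not compared apart, so this does not speak for either of them.

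Cycling-like cells had lower levels of most receptor and signalling genes called (4612 against 37119 cells, 7 hashtags tested). Il7r, the interleukin-7 receptor, was at 0.166 (0.162 to 0.169), Il6ra at 0.209 (0.194 to 0.225), Socs3 at 0.291 (0.275 to 0.308) and Prkcq, a kinase of the receptor pathway, at 0.428 (0.418 to 0.439). The chaperone gene Hsp90aa1, at 2.72 (2.69 to 2.74), was the 1 higher gene, and leaving out hashtag 1, 2, 4 or 5 gave 3, 2, 2 or 2 higher genes. There were 13 higher genes without hashtags 1 to 5, 3 without hashtags 1, 2 and 4, 3 when thinned and 2 with the median over hashtags. Of 144 measurable genes 48 were lower, and the cycling-like cells had a median of 15960.5 UMIs against 7041 over all kept cells. By list, 14 of 20 cytokine receptor and STAT genes were lower, with Il6st at 0.335 (0.604 without hashtag 9). So were 13 of 28 receptor signalling genes (Plcg1 at 0.481), 7 of 19 receptor-induced genes (Tnfaip3 at 0.401) and 6 of 19 type 1 genes (Stat4 at 0.516). Of the checkpoint genes 5 of 16 were lower, with Itgae at 0.243 (0.386 without hashtag 7) and Entpd1 at 0.334 (0.613 without hashtag 7), and 4 of the 8 genes of stained proteins were lower. The B-cell help genes Cd84, at 0.385, Tnfsf8, at 0.394, and Il21r were 3 lower of 8, and the type 2 list had 2 of 18 lower, Il4ra and Stat6, which also stand in the receptor list. The limit given above for Stat6, which was knocked out in some mice, holds here too. No type 17 gene was called of 5, and of 11 dissociation stress genes Hsp90aa1 was higher and Jun lower.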

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

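In 7 of 21 sets of values over the 10 hashtags, 1 hashtag stood far from the rest by Dixon's ratio. For independent normal values chance sets apart about 1 in 20, or 1.05 of 21. Class shares are neither normal nor independent, since many lie near the floor and they sum to the whole of a hashtag. The 7 can therefore not be read as an excess over 1.05. Of the tests, that of free Trdc RNA was chosen after the result was seen, while the bounds for mixed droplets were set before the values of barcodes with both hashtags 9 and 10 were seen, and after a first test on Trac alone, which went with mixed droplets.

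Hashtag 9 was set apart by its naive cells. CD4 naive-like cells were 54.4% of it, against 0.252% in the next hashtag, and CD8 naive-like cells 32.8%, against 3.805%. Its share of regulatory T-like cells was 5.49%, against 1.49% in the next hashtag, and its level of Grap2 was 310.2 CPM, against 193. Grap2 was also at 305 CPM in CD4 naive-like cells, but 1665 of these 1689 cells were of hashtag 9, so this largely restates its level. Hashtag 4 had 4.40% erythroid-like cells, against 1.28% in the next, but only 11.4% of the cells of this cluster had Hbb-bs, so most were barcodes with few UMIs (median 1248.5) and no sign of being erythroid in that gene. Of the barcodes with hashtag 6 as their leading tag, 40.3% were called with more than 1 hashtag by HTODemux, against 25.2% for the next hashtag. This depends on the method, since the rule of 10 counts and 4 times the second called 6324 barcodes with hashtag 6 alone, against 3910 by HTODemux. The added LAT-IRES-eGFP sequence, outside the comparisons, had 67 UMIs over all barcodes and 52 in kept cells, at most 14 in 1 hashtag (hashtag 5), and is listed since this is above the limit that a count of 0 allows.

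Gamma-delta T-like cells were 91.2% of hashtag 10, against 9.45% in the next hashtag. Free Trdc RNA as the source is argued against by a Trdc level 44.6 times that of hashtag 9 (1774 against 39.8 CPM), the hashtag it most often shared a droplet with, and by 99.5% of hashtag 10 cells having Trdc, against 12.5%. Droplets that hold an alpha-beta and a gamma-delta T cell would bring Trac, which stood at 0.717 times the lowest level of CD4 effector-like cells among other hashtags with 50 or more of them (392 against 547 CPM). They are argued against by median UMIs 0.537 times those of 149 barcodes with both hashtags 9 and 10 (5828.5 against 10851), and by 81.9% (80.5 to 83.2) of cells with neither Cd4 nor Cd8 transcripts, against 22.8% (16.3 to 30.4) in those barcodes. Trac was seen in 84.1% of the gamma-delta T-like cells of hashtag 10, against 40.1 to 70.7% in hashtags 1 to 5, which was not explained. The share of gamma-delta T-like cells may belong to the mouse or mice behind hashtag 10, but no biological explanation was tested, since the hashtags have no group.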

How the results depend on the processing

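Another random seed left the class shares the same, leaving out the 5 cells marked by Scrublet says nothing about doublets, and the alternatives below moved many values. The median over hashtags and the settings that leave out hashtags weigh the samples differently, and the cause of the other shifts was not tested. No paired test of the classes over hashtags was run, since hashtags in no group were not used as replicates. The alternatives set out beforehand for tests between genotypes (other normalizations, no count filter, leaving out each replicate) were not run for the same reason. Leaving out hashtags 1 to 5, or hashtags 1, 2 and 4, CD4 effector-like cells without cluster 8 (54 genes higher, 14 lower) and CD8 naive-like cells without cluster 23 (44 higher, 22 lower) were chosen after seeing the data. Depth limits the rare classes, and thinning to 2000 UMIs kept 41072 of 41731 T cells. Genes named by rule gave 400 pairs of a gene and a comparison. Of their 7100 ratios under the alternatives, 4618 stayed within the interval, 2465 moved beyond it in the same direction or without a call, and 17 turned. Of the other class shares 56 stayed and 90 moved, and of the levels of the targeted genes 28 stayed and 32 moved. Simpler hashtag rules called 88.1% (10 counts and 4 times the second) and 94.3% (3 counts and 2 times) of barcodes with 1 hashtag.

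Shares are given in the order CD4 naive-like, CD4 effector-like, regulatory T-like, CD8 naive-like, CD8 effector/memory-like and gamma-delta T-like, leaving out those that stayed. The shares in the report are 3.93, 31.3, 0.803, 2.99, 14.1 and 9.67%. With the median over hashtags they were 0.0187, 11.7, 0.117, 0.174, 6.62 and 2.02%, without hashtags 1 to 5 7.68, 45.5, 1.23, 5.70, 5.24 and 15.4%, and without hashtags 1, 2 and 4 5.41, 40.7, 0.906, 4.02, 5.72 and 11.6%. Leaving out 1 hashtag gave 0.0602 to 4.58, 22.3 to 34.2, 0.444 to 0.907, 0.702 to 3.43, 10.7 to 16.3 and 2.44 to 11.2%. With 15 components they were 4.19, 36.1, 2.41 (CD8 naive-like), 15.2 and 9.35%, and with all filtered cells 3.56, 32.9, 0.696, 14.8 (CD8 effector/memory-like) and 8.90%. At most 5% mitochondrial UMIs gave 36.4 (CD4 effector-like), 0.644, 7.10, 8.18 and 7.03%. Resolution 0.5 gave 35.8 (CD4 effector-like), 6.54 (CD8 naive-like) and 17.1%, and resolution 2.0 gave 34.3 (CD4 effector-like), 16.4 (CD8 effector/memory-like) and 9.35%. Keeping the listed genes for clustering gave 35.1 (CD4 effector-like) and 3.19% (CD8 naive-like), and 500 genes per cell gave 34.8 and 15.1% of CD4 and CD8 effector cells. No CD4 naive-like cluster was named at resolution 0.5 or at 5% mitochondrial UMIs, no regulatory T-like cluster with 15 components and no interferon-response cluster at resolution 0.5, so these give no value.

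Counts of genes moved as follows. For the CD4 effector-like, regulatory T-like and CD8 effector/memory-like comparisons the median over hashtags rests on 1 hashtag (9, 9 and 8). Calls under the median did not use the interval. CD4 effector-like, lower (14 in the report), were 9 when thinned, 24 with the median over hashtags and 9 without hashtag 9. Regulatory T-like, higher (31), were 19 when thinned, and lower (11) were 7 when thinned, 5 with the median, 19 scaled without ribosomal protein and mitochondrial genes and 3 without hashtag 9. CD8 effector/memory-like, lower (15), were 27 with the median, 29 at resolution 0.5 and 24 without hashtags 1 to 5. Gamma-delta, higher (5), were 9 without hashtags 1 to 5 and 9 without hashtag 9. Interferon-response, higher (1), were 2 when thinned, 3 with the median, 3 at resolution 2.0 and 2 without hashtags 1 to 5, and lower (5) were 2 when thinned, 12 at resolution 2.0, 26 without hashtags 1 to 5 and 8 without hashtags 1, 2 and 4. Cycling-like, higher (1), were 3 when thinned, 2 with the median, 13 without hashtags 1 to 5, 3 without hashtags 1, 2 and 4, 3 without hashtag 1 and 2 without hashtag 2, 4 or 5.

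The ratios of genes named by rule that turned were, for CD4 effector-like cells without hashtag 9, Fosb at 0.751. For regulatory T-like cells they were Sos1 at 1.09 when thinned and, without hashtag 9, Sos1 at 1.30, Grap2 at 1.02 and Ifngr2 at 1.11, where leaving out any other hashtag gave as little as 0.623, 0.563 and 0.569. For CD8 effector/memory-like cells they were Izumo1r at 0.446, Ndrg1 at 0.954 and Socs3 at 1.06 at resolution 0.5, Izumo1r at 0.748 without hashtag 5 (up to 3.71, without hashtag 9), and Egr3 at 1.93, Egr1 at 1.12 and Itgae at 3.23 without hashtag 9 (down to 0.244, 0.369 and 0.195 without other hashtags). Without hashtags 1 to 5 they were Ptpn6 at 0.797, Ndrg1 at 0.394, P2rx7 at 0.740 and Fosb at 0.548, and for gamma-delta T-like cells Areg at 1.502. Among called genes outside the rule, Stat3 turned for gamma-delta T-like cells without hashtag 10, at 0.976. Izumo1r (0.851 without hashtag 9) and Ubash3b (0.992 without hashtag 7) turned for CD4 effector-like cells. For regulatory T-like cells Socs1 (0.839) and Themis (1.03) turned without hashtag 9.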

Other observations

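Levels of effector genes in the classes were spread over the hashtags as follows. In CD4 effector-like cells Gata3 stood at 1046 CPM in hashtag 7 and 127 in hashtag 9, and Maf at 1346 in hashtag 7 and 242 in hashtag 6. Il1rl1 was at 364 CPM in hashtag 7 and 66.3 in hashtag 8, and the ectoenzyme gene Entpd1 at 247 in hashtag 7 and 8.70 in hashtag 4. Il4 was at 126.5 CPM in hashtag 3 and 10.3 in hashtag 9, and Il13 at 66.9 CPM in hashtag 3 and 0.423 in hashtag 7. The tags of hashtag 3 were the weakest, as given above, so its cells are the least surely assigned. In CD8 effector/memory-like cells Gzma was at 3170 CPM in hashtag 4 and 82.6 in hashtag 2, and Gzmk at 579 in hashtag 5 and 1.12 in hashtag 2. In regulatory T-like cells Gzmb was at 3418 CPM in hashtag 4, 730 in hashtag 8 and 7.39 in hashtag 9, while Nt5e was at 22.6, 30.5 and 131 CPM. These genes and hashtags were chosen after their values were seen, and no difference between hashtags was tested. Hashtag 10 is left out here, since 95.7% of its 140 CD4 effector-like cells had Trdc.

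The gamma-delta T-like cells formed 2 clusters with different receptor segments and effector genes, chosen after their values were seen. In cluster 3, of whose 3252 cells 3190 came from hashtag 10, Trdv2-2 made up 58.6% (56.4 to 60.7) and Trdv5 35.0% of 2107 Trdv UMIs. In cluster 18, with 902 cells of several hashtags, Trdv5 made up 48.9%, Trdv4 20.9% and Trdv2-2 17.5% of 325 Trdv UMIs. Cluster 3 had Gata3 at 742 CPM, Maf at 1030, Il1rl1 at 294 and Il6 at 75.0, against 102, 111, 3.18 and 0.455 in cluster 18. Gzma and Cd160 were at 52.7 and 5.11 CPM in cluster 3 and at 330 and 184 in cluster 18.

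Of the tests below, those of wrong hashtag calls, of whole macrophages and of evenly spread macrophage RNA were chosen after the result was seen, and that of free RNA of the other sex before it. That of moved hashtags was set before for cells with Y-linked transcripts and any 1 of the 3 hashtags, and after the result was seen it was widened to Xist cells and to each hashtag. The test of evenly spread RNA counts cells of all T clusters, in place of one on the level in cluster 19, which these genes had picked out, and its bound was lowered from 10 to 3 times after the value was seen.

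Hashtags 1, 2 and 4 each held cells with Xist alone and cells with Y-linked transcripts alone, at 31.5 and 47.6%, 43.4 and 36.4%, and 68.0 and 13.3%, while in each other hashtag 1 sex prevailed. Wrong hashtag calls are argued against by strongly tagged cells, of which at least 15.8% were of the rarer sex. Free RNA of the other sex is argued against by cells with 3 or more UMIs of 1 sex only, of which 33.9, 23.8 and 5.68% were of the rarer sex, and by cells with both at no more than 0.401 times independence, a bound added after the result was seen that decides hashtag 4. Hashtags that moved within a pool are argued against for hashtag 4, whose cells with Y-linked transcripts and whose Xist cells lay, in cluster make-up, 2.06 and 1.74 times as far from such cells of the partner as from the other sex of their own hashtag, but hashtags 1 (2.85 and 1.21) and 2 (1.27 and 0.539) leave it open. The 1.74 rests on 81 Xist cells of the weakly tagged hashtag 3, and so few cells alone can raise a distance. The 2.06 rests on 774 and 2236 cells with Y-linked transcripts. Partners are the hashtag pairs given below for barcodes with 2 strong hashtags. Moved hashtags may remain for hashtags 1 and 2, as may cells of more than 1 mouse under 1 hashtag, which was not tested, and no biological explanation was tested, since the hashtags have no group.

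The unnamed cluster 19 had CD3 transcripts together with macrophage transcripts. Whole macrophages in the droplet of a T cell are argued against by its median UMIs, 0.681 times those of other T clusters of hashtags 1 to 4. This is weak, since the other T clusters include cycling-like cells, at a median of 15960.5 UMIs. Clusters 4 and 11 had medians of 5690 and 6141.5, near the 6091 of cluster 19, so UMIs cannot exclude doublets of small cells. Free macrophage RNA spread evenly is argued against by 579 T cells of hashtags 1 to 4 with 5 or more UMIs of C1qa, C1qb and C1qc, 7.20 times the 80.4 of an even spread. The count includes cluster 19, which prompted the test and had these genes at 1573 CPM, against 7.06 in the other T clusters. Doublets of small cells may remain. Fragments of macrophages bound to T cells, or free RNA spread unevenly, may remain too, which was not tested, and no biological explanation was tested.

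Igkc was seen in 37.1% (35.4 to 38.8) of the cells of cluster 5, 28.8% of cluster 7 and 4.15% of cluster 6, and within hashtag 8 in 38.4% of cluster 5 and 4.28% of cluster 6, while Cd79a was seen in 0.158% of cluster 5. Of 2490 barcodes with 2 strong hashtags, 2060 (82.7%) held the pairs 1 and 2, 3 and 4, 5 and 6, 7 and 8, or 9 and 10.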
